A study of Rattus norvegicus with 16 samples.

How the data were processed

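RNA of isolated rat glomeruli was measured by sequencing of directional libraries from 350 ng of total RNA, depleted of ribosomal and globin transcripts, in 16 samples. Per the labels, the processing used cutadapt, STAR, HTSeq 0.6.1p1 and DESeq2 with the genome build Rnor_6.0, and neither the role of each tool nor the annotation release was stated. The deposited table held 36351 genes with, per the file headers, raw read counts for 16 libraries, which were whole numbers and which served as the data here. The authors also gave a log2 fold change and an adjusted p-value per gene and pair of groups, for genes they marked as above background. How these fold changes were estimated and how the p-values were adjusted was not given in the sources used here. The authors' log2 fold changes and p-values were used only to count shared calls. They called 3748 genes for PAN against sham, 1774 for PAN+MP against PAN, 903 for PAN+Pio against PAN, 2813 for PAN+MP against sham, 1427 for PAN+Pio against sham and 235 for PAN+Pio against PAN+MP. Of these, 3003, 1370, 580, 1996, 786 and 105 were also called here, in the same direction for each gene. A further 16 per-sample columns held the same counts times 1 factor per library and were not used.

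Count columns were assigned to groups by their names, where the untreated disease group is written with the word high, whose meaning the labels do not give. The column names carry no replicate numbers, so a column could not be tied to a single sample title. One sham and one PAN+Pio column carry an extra tag, and results without these 2 libraries were computed as an alternative. Each group had 4 libraries. Gene symbols are those of the deposited table. No coordinates are given, because the annotation at hand was of another build.

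The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 17061, and libraries were scaled by TMM factors, which lay between 0.952 and 1.05. A single model with 1 term per group was fitted to the 16 libraries with glmQLFit, leaving 12 residual degrees of freedom, and each pair of groups was tested with glmQLFTest. The p-values were adjusted by the method of Benjamini and Hochberg over the tested genes, and a gene was called changed at an adjusted p under 0.05. Adjusted p for single genes and counts of changed genes are from this test unless another tool is named. Log2 fold changes are given with a standard error, taken as the size of the change over the square root of the F statistic. Levels are CPM, counts scaled to the TMM-adjusted library size, with the SD over 4 rats, and log2 levels used a prior count of 2.

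The total count per library was 22802109 to 32571877, and the 10 genes with the highest counts took 4.54% to 6.28% of it. Counting error is small at this depth for most tested genes. Replicates differed by far more, with a biological coefficient of variation of 19.4% and, over the 24 pairs of replicates, at least 11.2 times the variance that counting alone gives. A zero count and the precision of single counts reflect counting error only, since reads without molecular identifiers are not independent molecules. The first principal component of the 1000 most variable genes held 35.8% of their variance and the second 17.3%. The test was tested on simulated data with 200 changed genes. It recovered 78% of genes with a log2 change of 1 and 99% of those with 2 in PAN against sham, 68% and 98% in PAN+MP against PAN, and 70% and 98% in PAN+Pio against PAN. Among the 186, 87 and 86 genes called there, 9, 4 and 2 had no simulated change.

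A disease gene was counted as reversed when it was changed in PAN against sham and changed with the opposite sign under the drug against PAN. Since the PAN libraries enter both contrasts, the count was also taken in 50 simulated sets with no drug effect and with the PAN libraries split 2 and 2. Gene lists, 32 in number, were written from textbook knowledge of glomerular cells, matrix, nephrotic syndrome and both drugs, with markers of tubule, blood and fat as possible carry-over. In 31 of them at least 3 genes were measured, and the list of the mitochondrial genome had no measured gene. Each list was tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with a correlation estimated per list, and adjusted over the lists within a comparison. With the estimated correlation, the calls fell from 16 to 0 for PAN against sham, from 13 to 5 for PAN+MP against PAN and from 19 to 5 for PAN+Pio against PAN. A further planned test, fry of limma, called 14, 9 and 12 lists in these comparisons. It called 0 for PAN+MP against sham, 1 for PAN+Pio against sham and 0 between the drugs. Fry asks whether a list's members changed, without setting them against other genes, and its values are not given per list. Several genes stand in more than 1 list, and many adipocyte markers are also PPAR gamma targets. The score of a list in a library is the mean of its members' log2 levels, each centred over the libraries. Correlations of list scores were tested with 100000 permutations.

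The genes named in the text were chosen by a rule. For each of the 3 main comparisons these were the 5 largest changes each way among changed genes with a symbol, a mean log2 level of at least 1 and no overlap between the libraries compared, and up to 4 changed members per list with the smallest p, or 2 where none passed. For the overlap they were the 15 genes reversed by both drugs with the smallest larger p, and between the drugs the 5 largest changes each way. Nphs1, Fkbp5, Tsc22d3, Fabp4 and Angptl4 were among those always included, and not every gene the rule takes is named. The tests of genes and gene lists, the lists, this rule and the alternatives below, other than the last 3, were fixed before the data were examined. The correlations of list scores and the tests of explanations for the respiratory chain, striated muscle and clock genes were added later.

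The alternatives were DESeq2 1.42.0 with its own size factors, RLE scaling in place of TMM, no filter beyond a total above 0, a filter of 1 CPM in 4 samples, a fit of only the groups compared, a minimum fold of 1.5 and leaving out each library in turn. The proximal tubule score as a covariate, leaving out the 2 tagged libraries, and limma-voom with sample quality weights were added after the data were seen.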

Results

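Glomeruli, the filtering units of the kidney, were isolated from rats on day 11 of a nephrotic syndrome model, and their RNA was sequenced after depletion of ribosomal and globin transcripts. There were 4 groups of 4 rats. Sham rats served as healthy controls. PAN rats received puromycin aminonucleoside, a podocyte toxin, at 50 mg/kg by tail vein. PAN+MP rats also received methylprednisolone, a glucocorticoid, at 15 mg/kg daily. PAN+Pio rats also received pioglitazone, an agonist of the nuclear receptor PPAR gamma, at 10 mg/kg daily. The stated purpose was to find which disease-induced changes each drug reverses, and which are reversed by both, with attention to the extracellular matrix of the glomerulus. The 16 libraries held 22802109 to 32571877 counted reads each. The mean total per group was 24226865 ± 1227357 reads in sham, 26869638 ± 1558851 in PAN, 30816221 ± 2496952 in PAN+MP and 25484357 ± 1047354 in PAN+Pio (SD, n = 4). Libraries are named by group and by their order among the count columns, which is a name only.

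PAN was compared with sham to learn what the disease model changes. Most measured cell division genes were higher in PAN, as were part of the genes of the contractile and intermediate filament cytoskeleton and of the extracellular matrix and its proteases, and several podocyte and endothelial genes were lower. Tpx2, a spindle assembly factor, rose from 9.57 ± 1.84 to 41.8 ± 9.20 CPM (SD, n = 4), where CPM is the read count scaled to library size. Des, the intermediate filament protein desmin, rose from 156 ± 30.3 to 919 ± 300.2 CPM. Magi2, a scaffold protein of the podocyte slit diaphragm, fell from 547 ± 106 to 101 ± 28.8 CPM. In all, 3231 of the 17061 tested genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1777 of them higher and 1454 lower, and 890 by at least 2-fold. The count was 2039 without Sham library 1 and 1978 without PAN library 3. The excess of higher genes was not steady, with 1415 higher and 1424 lower without Sham library 3, and 1435 and 1516 without Sham library 4.

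The largest rises in PAN included genes best known from striated muscle. Synpo2l, an actin-associated protein of the sarcomere, rose from 11.3 ± 3.60 to 478 ± 95.6 CPM (SD, n = 4), a log2 fold change of 5.41 ± 0.43 (SE) with an adjusted p of 1.83e-06 in edgeR's test. Ttn, the giant sarcomere protein titin, rose by 4.89 ± 0.56 on the log2 scale. Wfdc1, a secreted protein with a protease inhibitor domain, rose by 4.92 ± 0.45, Adamts14, a procollagen peptidase, by 4.78 ± 0.33, and Camkv, a kinase-like calmodulin-binding protein, by 4.38 ± 0.29. Acta1, skeletal muscle actin, stood at 0.0203 CPM in sham, too near 0 for a fold, and at 11.0 ± 9.17 CPM in PAN. Among the largest falls, Nmbr, the receptor of neuromedin B, went from 17.4 to 0.285 CPM, a log2 fold change of -5.90 ± 0.50 with an adjusted p of 3.09e-06. Prrt2, a membrane protein best known from synapses, fell by 3.79 ± 0.41, Igsf10, an immunoglobulin superfamily member, fell by 3.35 ± 0.40, Adrb1, the beta-1 adrenergic receptor, fell by 3.04 ± 0.40, and Dbp, a transcription factor of circadian output, fell by 2.98 ± 0.47. The 10 named genes other than Acta1 were ranked only among genes whose PAN and sham libraries did not overlap, so that separation is no result.

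**Figure D1:**
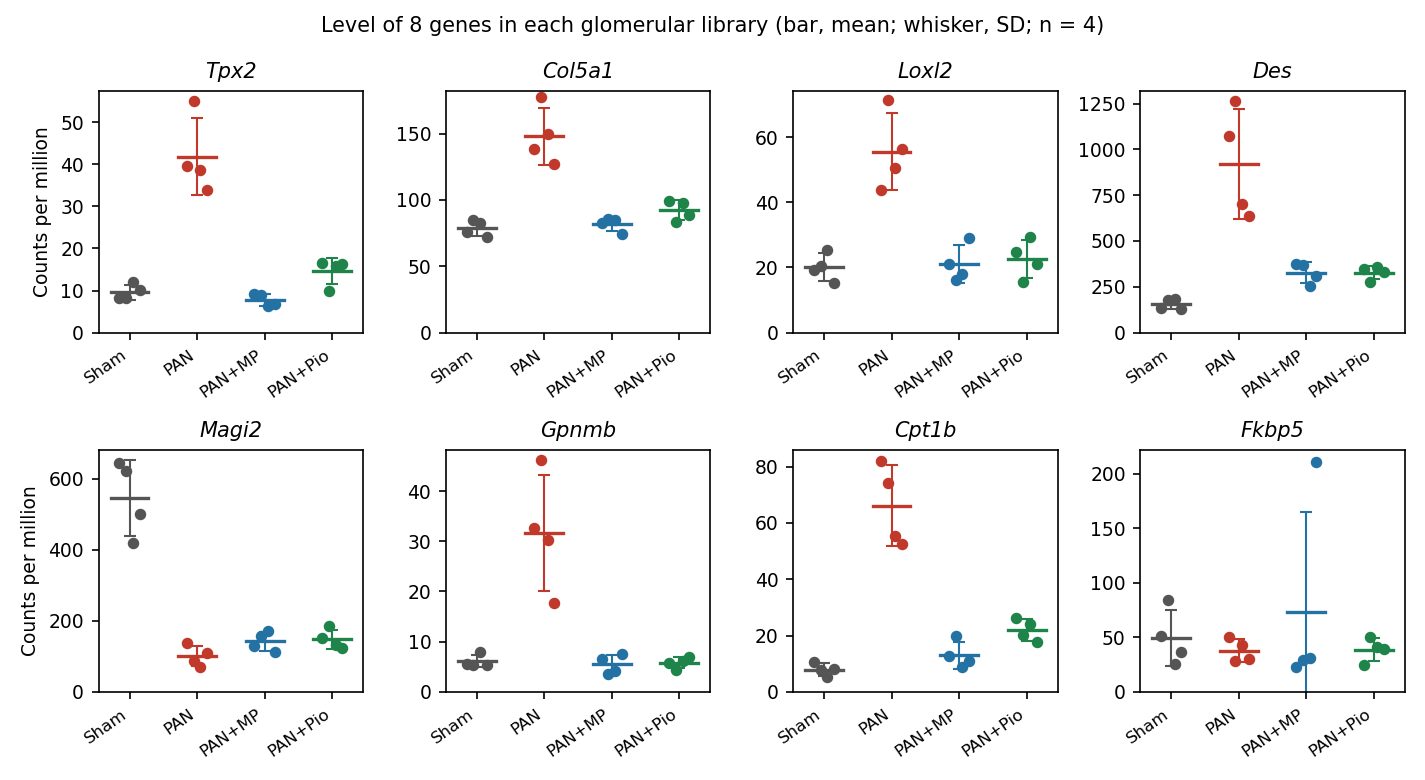
Levels of 8 genes in CPM, the read count scaled to library size (y axis, from 0) in each library of the 4 groups, one point per rat, with bars for the mean and whiskers for the SD (n = 4). Tpx2, Col5a1, Loxl2, Des, Gpnmb and Cpt1b were high in PAN and lower under both drugs, Magi2 was low in all 3 PAN groups, and Fkbp5 was high in 1 PAN+MP library, whose group's whisker would run below 0 and stops at the axis.

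Cell division genes moved as a block in PAN. Of 32 measured genes of DNA replication and mitosis, 30 rose and none fell (31 and 0 adjusted over the list alone), with a median log2 fold change of 1.99. Tpx2 rose by 2.13 ± 0.20, Bub1b, a kinase of the spindle checkpoint, by 2.41 ± 0.25, and Ccne1, cyclin E1, by 2.59 ± 0.30 (SE, n = 4). Targets of p53 rose with them, 7 of 20 measured, while 1 fell (8 and 2 adjusted over the list alone). Cdkn1a, the cell cycle inhibitor p21, rose by 1.99 ± 0.23, Ccng1, cyclin G1, by 1.64 ± 0.16, and Phlda3, a p53-induced repressor of Akt, by 1.30 ± 0.12. The median of the p53 list was 0.36. Against all other genes, camera's test gave an adjusted p of 6.56e-41 for the cell cycle list and 2.25e-05 for the p53 list. Neither call held when the correlation between members was estimated, with an adjusted p = 0.0962 with an estimated correlation for both lists.

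Part of the cytoskeleton genes that change in injured podocytes rose in PAN. Of 26 measured, 14 rose and none fell (15 and 1 adjusted over the list alone), and 9 rose without Sham library 1. Their median log2 fold change was 0.38, with an adjusted p of 5.03e-09 by camera and an adjusted p = 0.169 with an estimated correlation. Des rose by 2.55 ± 0.21, Flna, the actin crosslinker filamin A, by 0.88 ± 0.11, and Nes, the podocyte intermediate filament nestin, by 0.83 ± 0.10 (SE, n = 4). Of 16 mesangial and smooth muscle genes, 5 rose and 1 fell (6 and 2 adjusted over the list alone), with a median of 0.32, an adjusted p of 0.00227 and an adjusted p = 0.23 with an estimated correlation. Tagln, the smooth muscle actin-binding protein transgelin, rose by 2.69 ± 0.25.

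Podocyte genes went both ways. Of 30 measured markers, 6 rose and 8 fell (6 and 10 adjusted over the list alone), with a median log2 fold change of -0.18 and an adjusted p of 0.125 by camera. Magi2 fell by 2.43 ± 0.21, and Pla2r1, the phospholipase A2 receptor, fell by 1.14 ± 0.24. Enpep, the podocyte surface enzyme aminopeptidase A, rose by 1.36 ± 0.18. Nphs1, the slit diaphragm protein nephrin, stood at -0.28 ± 0.17 with an adjusted p of 0.259 (SE, n = 4). Of 17 glomerular endothelial genes, 8 fell and none rose (11 and 2 adjusted over the list alone), with a median of -0.40, an adjusted p of 0.0014 and an adjusted p = 0.413 with an estimated correlation. Emcn, the capillary sialomucin endomucin, fell by 0.70 ± 0.14, and Tie1, an endothelial receptor kinase, fell by 0.59 ± 0.14. The endothelial count was 4 without Sham library 1 or PAN library 3, and 5 without PAN library 1 or PAN library 4. Of 12 parietal epithelial genes, 2 rose and 1 fell, with a median of -0.14 and an adjusted p of 0.78.

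Matrix genes rose more often than they fell. Of 39 measured interstitial matrix genes, 16 rose and 1 fell (18 and 3 adjusted over the list alone), with a median log2 fold change of 0.40, an adjusted p of 9.06e-05 by camera and an adjusted p = 0.2 with an estimated correlation. Col1a1, a chain of fibrillar collagen I, rose from 14 ± 4.06 to 215 ± 191 CPM (SD, n = 4), by 3.94 ± 0.60 on the log2 scale. Col5a1, a collagen V chain, rose by 0.91 ± 0.10, and Loxl2, a collagen crosslinking enzyme, by 1.47 ± 0.22. Of 36 matrix remodelling enzymes and inhibitors, 14 rose and 1 fell (15 and 3 adjusted over the list alone), with a median of 0.28, an adjusted p of 2.69e-04 and an adjusted p = 0.169 with an estimated correlation. Timp2, an inhibitor of metalloproteinases, rose by 1.26 ± 0.12, and Ctsl, the protease cathepsin L, rose by 0.94 ± 0.15. Of 17 basement membrane genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of 0.09 and an adjusted p of 0.574. Agrn, the basement membrane proteoglycan agrin, fell by 0.47 ± 0.10. In the TGF beta list, 2 of 23 genes rose and 4 fell, with a median of 0.04 and an adjusted p of 0.724 for lower values. The interstitial matrix count was 10 without Sham library 1 and 11 without PAN library 3, and the basement membrane count was 1 without Sham library 1.

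Some macrophage markers were higher in PAN. Of 18 measured, 6 rose and 1 fell (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.62, an adjusted p of 0.0014 by camera and an adjusted p = 0.48 with an estimated correlation. Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 2.38 ± 0.28, and Cx3cr1, the fractalkine receptor, by 0.92 ± 0.23 (SE, n = 4). Among 25 inflammatory NF-kB targets, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.36, an adjusted p of 0.0407 and an adjusted p = 0.424 with an estimated correlation. Ptgs2, cyclooxygenase 2, rose by 0.78 ± 0.14. The macrophage count was 3 without Sham library 1, 4 without Sham library 2, 4 without PAN library 2 and 3 without the 2 libraries whose column names carry an extra tag. The inflammatory count was 3 without Sham library 1 and 2 without PAN library 3. Of 24 interferon response genes none passed edgeR's test, 6 had an unadjusted p under 0.05 and 3 passed in DESeq2. Their median was -0.46, with an adjusted p of 0.009 and an adjusted p = 0.741 with an estimated correlation. Complement genes changed in 4 of 18 cases, 3 higher and 1 lower, with an adjusted p of 0.179, and that count was 1 without Sham library 1, 2 without Sham library 3, 2 without PAN library 3 and 7 without PAN library 2.

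Some genes of lipid handling and more of those of the mitochondrial respiratory chain were also higher in PAN. Of 28 PPAR gamma targets 10 rose and none fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.74, an adjusted p of 1.28e-06 by camera and an adjusted p = 0.169 with an estimated correlation. Cpt1b, the muscle form of the mitochondrial fatty acid importer carnitine palmitoyltransferase, rose from 7.91 ± 2.21 to 66.0 ± 14.4 CPM (SD, n = 4), by 3.06 ± 0.26 on the log2 scale. Gpd1, glycerol-3-phosphate dehydrogenase, rose by 1.71 ± 0.22, Angptl4, an inhibitor of lipoprotein lipase, by 2.12 ± 0.52, and the fatty acid binding protein Fabp4 by 2.81 ± 0.71 with an adjusted p of 0.0124. Cidea, a lipid droplet protein of the adipocyte list, rose by 3.22 ± 0.47. In that list 2 of 8 genes rose and none fell (4 and 0 adjusted over the list alone), with a median of 0.78, an adjusted p of 0.0407 and an adjusted p = 0.2 with an estimated correlation. Of 30 oxidative phosphorylation genes 19 rose and none fell (26 and 0 adjusted over the list alone), with a median of 0.46, an adjusted p of 6.75e-10 and an adjusted p = 0.413 with an estimated correlation. Cox6a1 and Cox8a, subunits of cytochrome c oxidase, rose by 0.78 ± 0.11 and 0.93 ± 0.15. The oxidative phosphorylation count was 11 without Sham library 1, 10 without Sham library 3 and 9 without PAN library 3.

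Some fatty acid oxidation genes and NRF2 targets were higher as well. Of 26 fatty acid oxidation genes 5 rose and none fell (7 and 0 adjusted over the list alone), with a median of 0.34, an adjusted p of 5.67e-04 by camera and an adjusted p = 0.611 with an estimated correlation. Of 19 NRF2 targets 6 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.30, an adjusted p of 0.0012 and an adjusted p = 0.413 with an estimated correlation. Gpx2, a glutathione peroxidase, rose by 1.31 ± 0.17, and Ftl1, the ferritin light chain, by 1.13 ± 0.18 (SE, n = 4). The fatty acid oxidation count was 2 without Sham library 1, 3 without Sham library 3, 1 without PAN library 3 and 12 without PAN library 2. The NRF2 count was 3 without Sham library 1 or PAN library 3.

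Markers of the proximal tubule, a segment that can be carried over when glomeruli are isolated, varied between libraries together with these groups. Their mean log2 score was -0.45 ± 0.53 in sham and 0.04 ± 1.04 in PAN (SD, n = 4), lowest in PAN library 2 at -1.44 and highest in PAN library 3 at 0.98. None of the 17 markers passed edgeR's test in PAN against sham, 4 had an unadjusted p under 0.05 and 2 passed in DESeq2, with a median log2 fold change of 0.62 and an adjusted p of 0.0652 by camera. Across the 16 libraries the oxidative phosphorylation score rose with the tubule score, with Pearson's r of 0.794 (permutation p = 2.3e-04, adjusted 0.0023 over 30 lists) and Spearman's rho of 0.83 (permutation p = 2e-04). Leaving out PAN library 2 and Sham library 3, the farthest from the median, gave r of 0.843, and within groups r was 0.837. For fatty acid oxidation r was 0.877 (permutation p = 2e-05, adjusted 6e-04), rho was 0.871 (permutation p = 3e-05), and r was 0.883 without those libraries. For NRF2 targets r was 0.824 (permutation p = 1.5e-04, adjusted 0.00225), rho was 0.812 (permutation p = 2.6e-04), and r was 0.903 without those libraries. The distal nephron and parietal epithelial scores also rose with it, with r of 0.781 and 0.736 (permutation p = 5.6e-04 and 0.00182, adjusted 0.00342 and 0.0091), rho of 0.632 and 0.409 (permutation p = 0.0104 and 0.118), and r of 0.561 and 0.339 without those libraries. The endothelial score ran the other way, with r of -0.775 (permutation p = 5.7e-04, adjusted 0.00342), rho of -0.579 (permutation p = 0.0208) and r of -0.683 without those libraries. With the tubule score as covariate 5 endothelial genes were lower in PAN and 2 higher, with a median of -0.36. The other 24 lists did not pass, and these permutation tests were two-sided.

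The remaining lists in PAN against sham held up to 5 changed genes each. Of 15 distal nephron genes none passed edgeR's test, 1 had an unadjusted p under 0.05 and 1 passed in DESeq2, and the list's adjusted p by camera was 0.628. For 26 ribosomal protein genes these counts were 0, 2 and 1, with an adjusted p of 0.78, and for 6 neutrophil genes they were 0, 0 and 0, with an adjusted p of 0.628. Of 14 lymphocyte genes 1 fell, with an adjusted p of 0.335. Of 9 erythroid genes 1 fell, with a median log2 fold change of -0.48, an adjusted p of 0.0296 and an adjusted p = 0.48 with an estimated correlation. Of 29 glucocorticoid receptor targets 3 rose and 2 fell, with an adjusted p of 0.78, and 8 changed without Sham library 3. Fkbp5, a chaperone that glucocorticoids induce, stood at -0.38 ± 0.59 with an adjusted p of 0.676, and Tsc22d3, the glucocorticoid-induced leucine zipper, at -0.33 ± 0.30 with an adjusted p of 0.455. In the cholesterol synthesis and ER stress lists 2 genes each rose and none fell, with adjusted p of 0.125 and 0.192. Of 16 kidney injury genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), with an adjusted p of 0.303. Havcr1, the injury molecule KIM-1, rose from 0.351 to 3.95 CPM, and Timp1 rose by 0.55 ± 0.11. Of 22 immediate early genes 1 rose and 4 fell, with an adjusted p of 0.182. The kidney injury count was 3 without Sham library 1, Sham library 3 or PAN library 3. The immediate early count was 3 without Sham library 1, and 2 without PAN library 1 or PAN library 3.

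**Figure D2:**
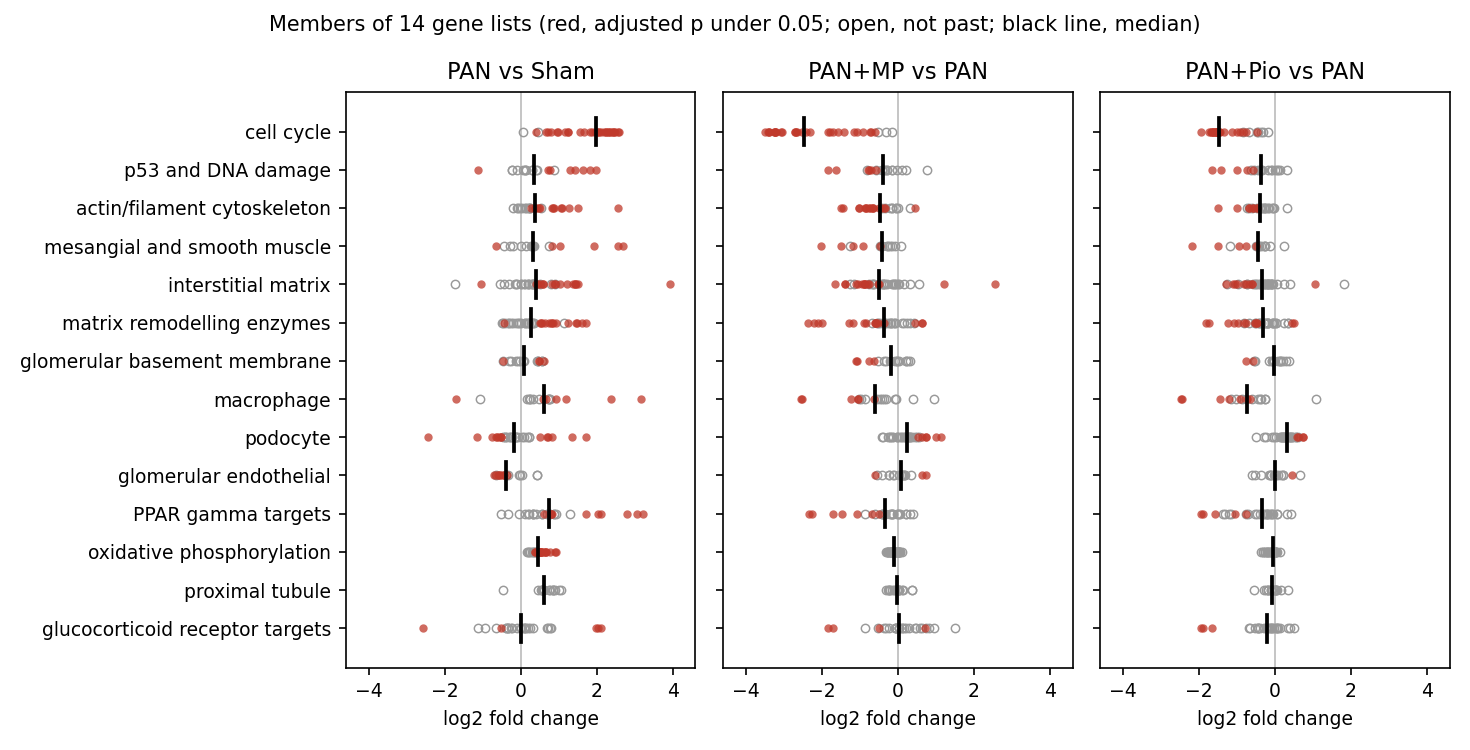
Log2 fold change (x axis) of each measured member of 14 gene lists (y axis) in PAN against sham, PAN+MP against PAN and PAN+Pio against PAN, with red points for members with an adjusted p under 0.05, open points for the others and a black line for the list's median. The cell cycle median was 1.99, -2.47 and -1.47 in the 3 panels, and that of oxidative phosphorylation was 0.46, -0.10 and -0.06.

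PAN+MP was compared with PAN to learn what methylprednisolone changes in diseased glomeruli. Most cell division genes and part of the matrix, cytoskeleton and macrophage genes were lower under the drug, and a few podocyte genes were higher. For the macrophage and interstitial matrix lists the call was lost when the correlation was estimated. Tpx2 fell to 7.81 CPM on average. Des went from 919 ± 300.2 CPM in PAN (SD, n = 4) to 327 CPM on average. In all, 1470 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 564 higher and 906 lower, and 606 by at least 2-fold. The count was 963 without PAN library 2, 978 without PAN+MP library 2 and 946 without PAN+MP library 3.

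The largest rises under methylprednisolone were those of Nmbr, by 4.81 ± 0.49 on the log2 scale, Dbp, by 3.13 ± 0.47, Lpar1, a lysophosphatidic acid receptor, by 2.78 ± 0.60, Adrb1, by 2.74 ± 0.40, and Col8a2, a collagen VIII chain, by 2.56 ± 0.66 (SE, n = 4). The adjusted p of Col8a2 was 0.0224, and it was 0.0703 without PAN library 2, 0.0517 without PAN library 3 and 0.0953 without PAN+MP library 4. Among the largest falls, Wfdc1 fell by 3.75 ± 0.40, Fam64a, a mitotic protein, fell by 3.90 ± 0.49, Ttk, a spindle checkpoint kinase, fell by 3.65 ± 0.36, Cenpt, a kinetochore protein, fell by 3.62 ± 0.39, and Pbk, a mitotic kinase, fell by 3.61 ± 0.42. These 10 genes were ranked only among genes whose PAN+MP and PAN libraries did not overlap, so that separation is no result.

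Of the 32 cell cycle genes 29 fell and none rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -2.47. Camera gave an adjusted p of 7.35e-83 and an adjusted p = 0.0138 with an estimated correlation. Bub1b fell by 3.26 ± 0.26, Nusap1, a spindle protein, fell by 3.40 ± 0.29, and Tpx2 fell by 2.42 ± 0.20 (SE, n = 4). Of 20 p53 targets 6 fell and none rose (10 and 2 adjusted over the list alone), with a median of -0.38, an adjusted p of 6.48e-05 and an adjusted p = 0.0497 with an estimated correlation. Cdkn1a fell by 1.83 ± 0.23, and Eda2r, a p53-induced death receptor, fell by 1.62 ± 0.29. The p53 count was 3 without PAN+MP library 1, 2 or 3.

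Some matrix genes fell under methylprednisolone. Of 39 interstitial matrix genes 14 fell and 2 rose (15 and 2 adjusted over the list alone), with a median log2 fold change of -0.50, an adjusted p of 3.55e-07 by camera and an adjusted p = 0.0756 with an estimated correlation. Col5a1 fell by 0.86 ± 0.10, Col6a3, a collagen VI chain, fell by 1.39 ± 0.21, Eln, elastin, fell by 1.65 ± 0.26, and Loxl2 fell by 1.40 ± 0.22 (SE, n = 4). Of 36 remodelling genes 14 fell and 3 rose (16 and 4 adjusted over the list alone), with a median of -0.35, an adjusted p of 3.55e-07 and an adjusted p = 0.0497 with an estimated correlation. Adam12, a metalloproteinase, fell by 2.20 ± 0.27, and Mmp2, gelatinase A, fell by 1.28 ± 0.15. Of 17 basement membrane genes 4 fell and none rose (6 and 0 adjusted over the list alone), with a median of -0.18, an adjusted p of 0.0347 and an adjusted p = 0.332 with an estimated correlation. Col4a1 and Col4a2, the ubiquitous collagen IV chains, stood at -1.11 ± 0.18 and -1.06 ± 0.18, both past the threshold, and Nid1, nidogen, fell by 0.75 ± 0.14. The interstitial matrix count was 10 without PAN library 2 or PAN+MP library 3, and the remodelling count was 10 without PAN+MP library 3.

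Among 26 cytoskeleton genes 16 fell and 1 rose (18 and 2 adjusted over the list alone), with a median log2 fold change of -0.47, an adjusted p of 2.51e-13 by camera and an adjusted p = 0.0497 with an estimated correlation. Flna fell by 0.84 ± 0.11 and Des fell by 1.49 ± 0.21 (SE, n = 4). Of 16 mesangial and smooth muscle genes 5 fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.42, an adjusted p of 1.09e-06 and an adjusted p = 0.0497 with an estimated correlation. Tagln fell by 2.03 ± 0.25, and Acta2, smooth muscle actin, fell by 1.17 ± 0.19. Of 30 podocyte genes 6 rose and none fell (7 and 0 adjusted over the list alone), with a median of 0.23, an adjusted p of 4.48e-04 and an adjusted p = 0.568 with an estimated correlation. Foxd1, a transcription factor, rose by 1.13 ± 0.17, Vegfa, the vascular growth factor that podocytes secrete, by 0.74 ± 0.14, and Cdkn1c, the cell cycle inhibitor p57, by 1.02 ± 0.24. Nphs1 stood at 0.55 ± 0.17 with an adjusted p of 0.0581, which was 0.0351 without PAN library 4. The cytoskeleton count was 11 without PAN library 2, and the mesangial count was 3 without PAN library 2, PAN library 4 or any of PAN+MP libraries 1, 2 and 3.

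Among 18 macrophage genes 6 fell and none rose (11 and 0 adjusted over the list alone), with a median log2 fold change of -0.59, an adjusted p of 1.46e-06 by camera and an adjusted p = 0.332 with an estimated correlation. Gpnmb fell by 2.54 ± 0.28 and Cx3cr1 fell by 1.24 ± 0.23 (SE, n = 4). The macrophage count was 3 without PAN library 2 and 2 without PAN+MP library 3. Of 25 inflammatory NF-kB targets 4 fell and none rose, with an adjusted p of 0.147, and the count was 1 without any of PAN libraries 2 and 3 and PAN+MP libraries 2, 3 and 4. Of 24 interferon response genes 2 rose and none fell (5 and 0 adjusted over the list alone), with a median of 0.36, an adjusted p of 0.0024 and an adjusted p = 0.697 with an estimated correlation. These were Ifit3, by 1.81 ± 0.40, and the antiviral GTPase Mx2, by 1.42 ± 0.39. The adjusted p of Mx2 was 0.0326, and 0.123 without PAN+MP library 1, 0.0965 without PAN library 1, 0.077 without PAN library 2 and 0.0614 without PAN library 3. Complement genes changed in 3 of 18 cases, 1 higher and 2 lower, with an adjusted p of 0.285.

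Glucocorticoid receptor targets did not rise as a group under methylprednisolone. Of 29 measured, 1 rose and 3 fell (1 and 3 adjusted over the list alone), with a median log2 fold change of 0.05 and an adjusted p of 0.917 for lower values by camera. The member that rose was Arrdc2, an arrestin domain protein, by 0.72 ± 0.21 with an adjusted p of 0.0455, which lay between 0.0553 and 0.126 without any of PAN libraries 2, 3 and 4 or any of the 4 PAN+MP libraries. Among those that fell were Cdkn1a and Pdk4, a kinase that restrains pyruvate oxidation, which fell by 1.70 ± 0.48 with an adjusted p of 0.0362. The adjusted p of Pdk4 lay between 0.0597 and 0.126 without PAN library 1 or 2 or PAN+MP library 1, 2 or 3. Fkbp5 stood at 0.96 ± 0.59 with an adjusted p of 0.397, and Tsc22d3 at 0.58 ± 0.30 with an adjusted p of 0.295 (SE, n = 4). PAN+MP library 4 held 210.5 CPM of Fkbp5, against 22.4 to 31.1 CPM in the other PAN+MP libraries. The list's count was 2 without PAN library 1 or 3, and 1 without PAN library 2 or PAN+MP library 1, 2 or 3. Without PAN+MP library 4 it was 5, all lower.

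Among 28 PPAR gamma targets 7 fell under methylprednisolone and none rose (10 and 1 adjusted over the list alone), with a median log2 fold change of -0.34, an adjusted p of 0.00188 by camera and an adjusted p = 0.39 with an estimated correlation. Cpt1b fell by 2.34 ± 0.25 (SE, n = 4). Fabp4 fell by 2.26 ± 0.66 with an adjusted p of 0.044, which lay between 0.0749 and 0.131 without any of PAN libraries 1, 2 and 3 or PAN+MP libraries 1, 2 and 3. Angptl4 stood at -0.85 ± 0.48 with an adjusted p of 0.343, and without PAN+MP library 4 at -1.65 with an adjusted p of 0.0232. The PPAR gamma count was 2 without PAN library 1 or PAN+MP library 2 or 3, 3 without PAN library 2 and 4 without PAN+MP library 1. Of 30 oxidative phosphorylation genes none passed edgeR's test, 2 had an unadjusted p under 0.05 and none passed in DESeq2, and the list's adjusted p was 0.299. The 17 proximal tubule genes had 0 in each of these 3 counts, with an adjusted p of 0.571. Havcr1 fell by 3.46 ± 0.63, the single member of the kidney injury list to change, with an adjusted p of 0.81 for the list.

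The other lists in PAN+MP against PAN held up to 3 changed genes each. Of 17 endothelial genes 2 rose and 1 fell, with an adjusted p of 0.607 by camera. Erythroid genes had a median log2 fold change of 0.28, with 1 of 9 higher, an adjusted p of 0.0347 and an adjusted p = 0.568 with an estimated correlation. Of 22 immediate early genes 3 fell and none rose (4 and 0 adjusted over the list alone), with an adjusted p of 0.0347 and an adjusted p = 0.568 with an estimated correlation. In the TGF beta, lymphocyte and adipocyte lists 2 genes each fell and none rose, with adjusted p of 0.176, 0.571 and 0.299. In the fatty acid oxidation list 1 of 26 genes fell, with an adjusted p of 0.917. Of 6 neutrophil genes none passed edgeR's test, 1 had an unadjusted p under 0.05 and none passed in DESeq2, with a median of 1.02 and an adjusted p of 0.607. The neutrophil score stood at 1.85 in PAN+MP library 4, against -0.84 to 0.34 in the other 3 PAN+MP libraries.

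PAN+Pio was compared with PAN to learn what pioglitazone changes in diseased glomeruli. Most cell division genes and part of the matrix, cytoskeleton and macrophage genes were lower under this drug too, and a few podocyte genes were higher. The macrophage and interstitial matrix calls were again lost when the correlation was estimated. Tpx2 stood at 14.7 CPM on average and Des at 327 CPM. In all, 628 genes changed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 142 higher and 486 lower, and 309 by at least 2-fold. The count was 292 without PAN library 2, 276 without PAN+Pio library 2 and 382 without PAN+Pio library 4, and DESeq2 called 1076.

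The largest rises under pioglitazone were those of Nmbr, by 3.26 ± 0.50 on the log2 scale, Dpp10, a membrane protein of the dipeptidyl peptidase family, by 2.12 ± 0.42, Ttc22, a tetratricopeptide repeat protein, by 1.70 ± 0.18, Myh15, a myosin heavy chain, by 1.63 ± 0.29, and Igsf10, by 1.59 ± 0.39 (SE, n = 4). The adjusted p of Igsf10 was 0.0296, and it lay between 0.0548 and 0.0892 without any of PAN libraries 1, 2 and 4 or PAN+Pio libraries 1, 2 and 4. Wfdc1 fell by 4.07 ± 0.42, the replication-dependent histone gene Hist2h2aa3 fell by 2.82 ± 0.56, Gpnmb fell by 2.44 ± 0.28, Gprc5a, an orphan receptor, fell by 2.39 ± 0.36, and Gnat2, a transducin subunit, fell by 2.21 ± 0.37. These 10 genes were ranked only among genes whose PAN+Pio and PAN libraries did not overlap, so that separation is no result.

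Of the 32 cell cycle genes 25 fell and none rose (29 and 0 adjusted over the list alone), with a median log2 fold change of -1.47, an adjusted p of 2.61e-49 by camera and an adjusted p = 0.0213 with an estimated correlation. Tpx2 fell by 1.51 ± 0.19, Ccne1 fell by 1.96 ± 0.29 and Bub1b fell by 1.54 ± 0.23 (SE, n = 4). Of 20 p53 targets 5 fell and none rose (9 and 0 adjusted over the list alone), with a median of -0.36, an adjusted p of 1.12e-07 and an adjusted p = 0.0213 with an estimated correlation. Phlda3 fell by 0.99 ± 0.12 and Cdkn1a fell by 1.65 ± 0.23. The p53 count was 3 without PAN library 2 or 3 or PAN+Pio library 4, and 2 without PAN+Pio library 2.

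Some matrix genes fell under pioglitazone as well. Of 39 interstitial matrix genes 9 fell and 1 rose (14 and 2 adjusted over the list alone), with a median log2 fold change of -0.33, an adjusted p of 1.76e-08 by camera and an adjusted p = 0.0506 with an estimated correlation. Loxl1, an elastin crosslinking enzyme, fell by 0.76 ± 0.11, Col5a1 fell by 0.68 ± 0.10 and Loxl2 fell by 1.30 ± 0.22 (SE, n = 4). Of 36 remodelling genes 11 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.32, an adjusted p of 2.2e-08 and an adjusted p = 0.0213 with an estimated correlation. Ctss, the macrophage protease cathepsin S, fell by 1.23 ± 0.22, and Mmp2 fell by 0.81 ± 0.15. Of 17 basement membrane genes 2 fell and none rose (4 and 1 adjusted over the list alone), with a median of -0.03 and an adjusted p of 0.446. The interstitial matrix count was 5 without PAN library 2 or PAN+Pio library 4, and 6 without PAN+Pio library 2. The remodelling count was 5 without PAN library 2 or PAN+Pio library 4, 7 without PAN+Pio library 2, and 8 without PAN library 1, PAN library 3 or PAN+Pio library 1.

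Under pioglitazone 8 of 26 cytoskeleton genes fell and none rose (16 and 1 adjusted over the list alone), with a median log2 fold change of -0.38, an adjusted p of 4.51e-15 by camera and an adjusted p = 0.0295 with an estimated correlation. Des fell by 1.49 ± 0.21 and Flna fell by 0.68 ± 0.11 (SE, n = 4). Of 16 mesangial and smooth muscle genes 5 fell and none rose (10 and 0 adjusted over the list alone), with a median of -0.44, an adjusted p of 3.4e-10 and an adjusted p = 0.0213 with an estimated correlation. Tagln fell by 2.17 ± 0.25. Of 30 podocyte genes 4 rose and none fell (6 and 1 adjusted over the list alone), with a median of 0.31, an adjusted p of 8.98e-08 and an adjusted p = 0.233 with an estimated correlation. Vegfa rose by 0.74 ± 0.14. The adjusted p of Foxd1, at 0.73 ± 0.17, was 0.0236, and it lay between 0.063 and 0.0779 without PAN library 1 or 2 or PAN+Pio library 3 or 4. That of Thsd7a, a podocyte membrane protein, at 0.58 ± 0.15, was 0.0481, and it lay between 0.0759 and 0.142 when any 1 library other than PAN library 1 was left out. Nphs1 stood at 0.56 ± 0.17 with an adjusted p of 0.09. The cytoskeleton count was 3 without PAN library 2, 4 without PAN+Pio library 2 and 5 without PAN+Pio library 1. Leaving out any 1 of the 8 libraries other than PAN library 1 took the mesangial count to 2 or 3, and leaving out any other than PAN library 4 took the podocyte count to 1 or 2.

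Of the macrophage genes 7 of 18 fell and none rose (13 and 0 adjusted over the list alone), with a median log2 fold change of -0.75, an adjusted p of 7.77e-13 by camera and an adjusted p = 0.0729 with an estimated correlation. C1qb and C1qa, complement subunits made by macrophages, had log2 fold changes of -1.46 ± 0.32 and -1.22 ± 0.28 (SE, n = 4), with adjusted p of 0.0175 and 0.0226. For C1qb the adjusted p was 0.0515 without PAN library 1 and 0.0725 without PAN+Pio library 2, and for C1qa it lay between 0.0546 and 0.0881 without PAN library 1 or 2 or PAN+Pio library 2, 3 or 4. The macrophage count was 1 without PAN library 1 or PAN+Pio library 2, 2 without PAN library 2 or PAN+Pio library 4, 3 without PAN+Pio library 3, and 2 without the 2 libraries whose column names carry an extra tag. Of 18 complement genes 2 fell and none rose (4 and 0 adjusted over the list alone), with a median of -0.37, an adjusted p of 0.00432 and an adjusted p = 0.0993 with an estimated correlation. Of 25 inflammatory NF-kB targets 1 fell (3 adjusted over the list alone), with a median of -0.22, an adjusted p of 0.0252 and an adjusted p = 0.309 with an estimated correlation. Of 24 interferon response genes none passed edgeR's test, none had an unadjusted p under 0.05 and none passed in DESeq2, with an adjusted p of 0.401.

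PPAR gamma targets are genes that agonists such as pioglitazone induce in adipose tissue. Some fell here under pioglitazone, where 628 of 17061 tested genes changed. Of 28 measured, 5 fell and none rose (10 and 1 adjusted over the list alone), with a median log2 fold change of -0.35, an adjusted p of 2.49e-06 by camera and an adjusted p = 0.111 with an estimated correlation. Cpt1b fell by 1.59 ± 0.24, and Cd36, a fatty acid transporter, fell by 1.04 ± 0.22 (SE, n = 4). Ucp2, a mitochondrial carrier, fell by 0.77 ± 0.17, Pdk4 fell by 1.89 ± 0.48 and Angptl4 fell by 1.94 ± 0.51, with adjusted p of 0.0184, 0.0399 and 0.0454. Fabp4 stood at -1.32 ± 0.63 with an adjusted p of 0.325, and Cidea at -1.38 ± 0.39 with an adjusted p of 0.0631, which was 0.0184 without PAN+Pio library 1. Without single libraries, the adjusted p lay between 0.0513 and 0.0702 for Ucp2 (PAN library 1 or 2, PAN+Pio library 1), between 0.0634 and 0.125 for Pdk4 and between 0.0873 and 0.129 for Angptl4 (both for any of PAN libraries 1 to 3 and PAN+Pio libraries 1, 2 and 4). It was 0.0576 for Cd36 without PAN+Pio library 2, and 0.0504 for Cd36 and Ucp2 without PAN+Pio library 4. The PPAR gamma count was 1 without PAN+Pio library 4, 2 without PAN library 1 or 2, and 3 without PAN library 3 or PAN+Pio library 1 or 2. In the adipocyte list none of 8 genes passed edgeR's test, 1 had an unadjusted p under 0.05 and 1 passed in DESeq2, with a median of -0.46, an adjusted p of 0.0575 and an adjusted p = 0.171 with an estimated correlation. Glucocorticoid receptor targets included 3 genes that fell and none that rose, with a median of -0.21, an adjusted p of 0.00824 and an adjusted p = 0.505 with an estimated correlation. Fkbp5 stood at 0.04 ± 0.59 with an adjusted p of 0.987 and Tsc22d3 at -0.21 ± 0.30 with an adjusted p of 0.824.

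The remaining lists in PAN+Pio against PAN held up to 2 changed genes each. Plat, the tissue plasminogen activator, rose by 0.44 ± 0.11 (SE, n = 4), the single endothelial gene of 17 to change, with an adjusted p of 0.0417 that lay between 0.0567 and 0.129 without any of the 4 PAN libraries or PAN+Pio library 3 or 4. Havcr1 fell by 4.29 ± 0.69, 1 of 2 kidney injury genes that fell, with an adjusted p of 0.0191 by camera for that list and an adjusted p = 0.423 with an estimated correlation. Of 9 erythroid genes 1 rose (7 adjusted over the list alone), with a median log2 fold change of 0.72, an adjusted p of 8.01e-06 and an adjusted p = 0.111 with an estimated correlation. Distal nephron, immediate early, cholesterol and ER stress lists had no gene past edgeR's threshold, 1, 6, 2 and 1 genes at an unadjusted p under 0.05, and 1, 1, 0 and 0 in DESeq2. Their medians were 0.47, -0.27, 0.17 and -0.27, with adjusted p of 6.6e-04, 2.68e-04, 0.0191 and 0.00824. Each of these calls was lost when the correlation was estimated, with an adjusted p = 0.45, 0.17, 0.625 and 0.507 with an estimated correlation. The TGF beta list had 1 gene lower, with an adjusted p of 0.0485 and an adjusted p = 0.443 with an estimated correlation. Of 30 oxidative phosphorylation genes none passed edgeR's test, 2 had an unadjusted p under 0.05 and none passed in DESeq2, with an adjusted p of 0.142. The proximal tubule list had 0 in each of these counts, with an adjusted p of 0.57.

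The overlap of the drugs is the question the study names. Methylprednisolone reversed 886 of the 3231 disease genes, 589 that were higher in PAN and 297 that were lower, and moved 5 further in the disease direction. Pioglitazone reversed 532, 415 higher and 117 lower, and moved 0 further by edgeR's test. Both drugs reversed 475 genes, 377 of them higher in PAN and 98 lower, which is 14.7% of the disease genes. Lists drawn independently would share 137.6 and 23.9 of these. Since the same PAN libraries enter every contrast, data with no drug effect were simulated 50 times, and they gave a mean of 0.02 reversed genes for methylprednisolone and 0 for pioglitazone and for both. Such data hold almost no call against PAN, with a mean of 0.04 genes higher and 0.04 lower under methylprednisolone. They therefore cannot show how much of the overlap the shared PAN libraries add when each drug has an effect. Leaving out 1 library took the count for both to 238 without PAN library 2 and 241 without PAN+Pio library 2, with 311 without PAN+Pio library 4. The count for pioglitazone was 262 without PAN library 2, 354 without PAN library 3, 250 without PAN+Pio library 2 and 336 without PAN+Pio library 4.

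Among the genes reversed by both drugs with the smallest adjusted p were Wfdc1, Gpnmb, Tagln, Tpx2 and Phlda3. Ttc22 fell by 1.25 on the log2 scale in PAN and rose by 1.72 under methylprednisolone and 1.70 under pioglitazone, and Tspan15, a tetraspanin, rose by 0.95 and 0.93. Trim72, a membrane repair protein of striated muscle, rose by 4.34 ± 0.40 in PAN (SE, n = 4) and stood at -3.28 under methylprednisolone and -3.01 under pioglitazone, and Ldb3, a sarcomere Z-disc protein, rose by 2.68 ± 0.24 and stood at -2.23 and -1.87. Acta1 stood at 0.0727 CPM under methylprednisolone and 0.242 CPM under pioglitazone. The cell division genes Mybl2, a transcription factor, H2afx, a histone variant, and Anln, anillin, had log2 fold changes of -2.44, -1.55 and -1.38 under methylprednisolone and -1.44, -1.10 and -1.19 under pioglitazone. The uncharacterised genes LOC684762 and LOC684828 stood at -1.61 and -2.19 under methylprednisolone and at -1.14 and -1.39 under pioglitazone.

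By gene group, both drugs reversed 24 of the 30 cell cycle genes changed in PAN, 9 of 17 interstitial matrix genes, 10 of 15 remodelling genes, 5 of 14 cytoskeleton genes, 4 of 7 macrophage genes, 3 of 6 mesangial genes and 4 of 8 p53 targets. They reversed 3 of 14 podocyte genes, 2 of 10 PPAR gamma targets and 1 of 8 endothelial genes. Of the 19 oxidative phosphorylation genes and 6 NRF2 targets higher in PAN, 0 were reversed by either drug in edgeR's test. Of the 14 cytoskeleton genes, methylprednisolone reversed 12 and pioglitazone 5. Tested directly between the drugs, none of the 26 cytoskeleton genes passed edgeR's test and 5 had an unadjusted p under 0.05, with a median log2 fold change of 0.10 and an adjusted p of 0.162 by camera, so the counts do not show that the drugs differ there.

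Across the 17061 tested genes, the log2 fold changes of the drugs against PAN were correlated, with Pearson's r of 0.756 and Spearman's rho of 0.659. Genes are not independent replicates, and the shared PAN libraries alone gave a mean r of 0.500 and a highest of 0.527 in simulated data. Those data lack differences that run through a whole library, so their highest r is no ceiling for real libraries. Regrouping the real PAN and drug libraries gave r up to 0.738, with a median of 0.506. With each drug compared with a different pair of PAN libraries, in the 6 possible ways, r lay between 0.384 and 0.525. The simulated and regrouped values share PAN libraries, so they are no null for these splits. The covariance was 0.109 to 0.142 in these splits. With shared libraries it was 0.170, and 0.131 after subtracting the simulated 0.0393. With PAN against sham taken on one pair of PAN libraries and both drugs compared with the other pair, 42 to 336 genes were reversed by both drugs over the 6 ways. Methylprednisolone reversed 413 to 546 genes there and moved 0 to 49 further in the disease direction. Pioglitazone reversed 45 to 361 and moved 0 to 10 further.

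**Figure D3:**
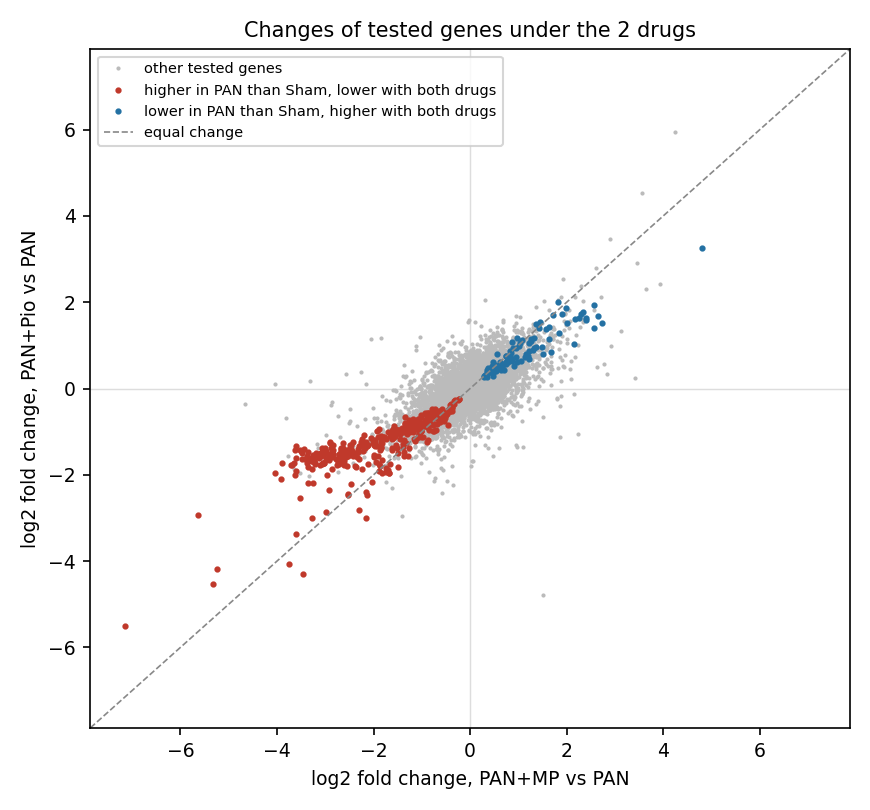
Log2 fold change against PAN under methylprednisolone (x axis) and under pioglitazone (y axis), one point per tested gene, with the 377 genes higher in PAN and lower with both drugs in red, the 98 lower in PAN and higher with both in blue, other tested genes in grey, and a dashed line for equal change. Pearson's r across genes was 0.756, where simulated data with shared PAN libraries and no drug effect gave a mean of 0.500. Regrouping the real PAN and drug libraries gave r up to 0.738.

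PAN+MP was compared with sham to learn what still differs from healthy glomeruli under methylprednisolone. Of the 3231 disease genes 1086 were still called in the same direction. Of 30 oxidative phosphorylation genes 9 were higher than in sham and none lower (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.36, and NRF2 targets were higher in 6 of 19 cases, with a median of 0.35. Endothelial genes were lower in 7 of 17 cases and higher in 1, with a median of -0.45. Of 32 cell cycle genes 4 were lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -0.45 and an adjusted p = 0.873 with an estimated correlation. Immediate early genes, which respond to tissue handling, were lower in 6 of 22 cases (9 adjusted over the list alone), with a median of -0.44. The proximal tubule list had a median of 0.69 with none of 17 genes past edgeR's threshold and 1 at an unadjusted p under 0.05. Camera's adjusted p was 1.72e-09 for oxidative phosphorylation, 6.24e-04 for NRF2 targets, 0.00303 for endothelial genes, 0.00113 for the cell cycle, 2.73e-04 for immediate early genes and 0.00433 for the proximal tubule. None of the 9 lists called in this comparison kept its call when the correlation was estimated, the smallest being an adjusted p = 0.778 with an estimated correlation. In all, 2167 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1020 higher and 1147 lower. The count was 726 without Sham library 1, 1327 without Sham library 3, 1309 without PAN+MP library 1, 1012 without PAN+MP library 2 and 988 without PAN+MP library 4. Higher genes outnumbered lower ones without Sham library 1 (388 and 338), without PAN+MP library 4 (526 and 462), with only the groups compared (944 and 927) and with the tubule score as covariate (463 and 313).

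PAN+Pio was compared with sham in the same way. Of the disease genes 704 were still called in the same direction, and 505 were still called under both drugs. Oxidative phosphorylation genes were higher in 9 of 30 cases with none lower (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.37, and endothelial genes were lower in 3 of 17 (9 adjusted over the list alone), with a median of -0.47. Of 32 cell cycle genes 1 was higher and none lower (9 and 0 adjusted over the list alone), with a median of 0.56. Immediate early genes were lower in 6 of 22 cases with a median of -0.51. Of 17 proximal tubule and 15 distal nephron genes none passed edgeR's test, and 1 and 7 had an unadjusted p under 0.05, with medians of 0.61 and 0.74. Magi2 averaged 143 CPM under methylprednisolone and 148 CPM under pioglitazone, against 547 CPM in sham, and Synpo2l averaged 158 and 242 CPM, against 11.3 CPM. Camera's adjusted p was 1.13e-11 for oxidative phosphorylation, 1.83e-04 for endothelial genes, 7.41e-07 for the cell cycle and for immediate early genes, 0.00324 for the proximal tubule and 3.66e-04 for the distal nephron. None of the 13 lists called kept its call when the correlation was estimated, the smallest being an adjusted p = 0.429 with an estimated correlation. In all, 867 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 511 higher and 356 lower. The count was 334 without Sham library 1, 528 without Sham library 3, and 336, 396 and 403 without PAN+Pio libraries 1, 3 and 4. Lower genes outnumbered higher ones in DESeq2 (881 and 843) and without Sham library 4 (428 and 403).

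PAN+Pio was compared with PAN+MP directly, which tests whether the drugs differ. Of the cell division genes 13 of 32 were higher under pioglitazone than under methylprednisolone and none lower (23 and 1 adjusted over the list alone), with a median log2 fold change of 0.96, an adjusted p of 9.86e-42 by camera and an adjusted p = 0.158 with an estimated correlation. The histone genes Hist1h2bl, Hist1h2ak and Hist1h2bk, whose near-identical copies can share reads, were higher by 2.29 ± 0.28, 2.04 ± 0.30 and 1.98 ± 0.27, and Esco2, an acetyltransferase of sister chromatid cohesion, by 2.05 ± 0.37 (SE, n = 4). Arntl, the core clock activator BMAL1, was higher by 2.51 ± 0.46, while the clock genes Tef, Per2 and Cry1 stood at -1.86 ± 0.34, -1.83 ± 0.31 and -1.72 ± 0.36. The time of day of collection is not given in the sources used here, so these clock values are not called drug effects. Art3, an ADP-ribosyltransferase family member, stood at -2.06 ± 0.39 and F3, tissue factor, at -2.04 ± 0.41. Of the 411 disease genes reversed by methylprednisolone and not by pioglitazone, 21 differed between the drugs, and of the 57 reversed by pioglitazone alone 2 did. In all, 108 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 73 higher and 35 lower under pioglitazone, and DESeq2 called 286. The edgeR count was 0 without PAN+MP library 2 or 3, with 1308 and 1263 genes at an unadjusted p under 0.05, and it was 11, 6, 19 and 24 without PAN+MP library 4 and PAN+Pio libraries 1, 3 and 4. Each of the 10 genes named here lost its call without PAN+MP library 2 and without PAN+MP library 3.

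The other lists called between the drugs had no gene past edgeR's threshold. Interferon response genes had a median log2 fold change of -0.41, with 5 of 24 at an unadjusted p under 0.05 and an adjusted p of 2.47e-04 by camera. For cholesterol synthesis genes the median was 0.24, with 3 of 21 at an unadjusted p under 0.05 and an adjusted p of 4.34e-04. For glucocorticoid receptor targets it was -0.19, with 5 of 29 and an adjusted p of 0.00406. For basement membrane genes it was 0.11, with 4 of 17, and for kidney injury genes -0.27, with 2 of 16, each with an adjusted p of 0.0239. With an estimated correlation the adjusted p was 0.735 for the basement membrane list and 0.963 for the other 4 of these. Within PAN+MP the glucocorticoid score ran from -0.30 to 0.71, highest in library 4, and the interferon score from -0.41 to 1.04, highest in library 1.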

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

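The test of tubule carry-over as the whole of the rise in respiratory chain genes, the test of a larger mesangial share, and the proximal tubule score as a covariate were chosen only after the results were seen. The 12 striated muscle genes and the clock genes weighed here were picked after their values were seen, so what is said of both is a hypothesis.

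Oxidative phosphorylation genes were higher in PAN than in sham, 19 of 30 with a median log2 fold change of 0.46. More proximal tubule carried over into the PAN libraries is a candidate explanation, because the list's score followed the tubule score across libraries. With the tubule score as covariate the median was 0.344, between the bounds of 0.23 and 0.35 and just short of the bound against carry-over. The bounds were set before this test was run but after the rise was seen, and the lower one follows from the median of 0.46. This test leaves open whether carry-over contributed. With the same covariate 17 members were still higher in edgeR's test, which argues against carry-over as the whole of the rise. An effect of the disease on respiratory chain genes stays open.

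Genes of striated muscle were higher in PAN, 12 of 12 with a median log2 fold change of 4.09 and a lowest of 2.55, and 10 of them fell under methylprednisolone and 8 under pioglitazone. Skeletal muscle carried over into the PAN preparations would bring its abundant transcripts, but 12 of these rose by 18.9 CPM together, against 466 CPM for Synpo2l alone, and Ckm and Pvalb had no counts in either group. The skeletal muscle values argue against that source as the whole of the rise. A larger share of mesangial and smooth muscle cells would raise their markers alike. The median of that list without Des, the lowest of the 12 genes at 2.55, was 0.31, while its members Tagln and Cnn1 rose by 2.69 and 1.92. Since the 12 genes were picked after their values were seen, a whole list's median would tend to lie below them. This comparison therefore cannot decide on a larger mesangial share. A change of expression within glomerular cells of PAN rats may be the source, which was not tested in itself.

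Clock genes shifted between PAN and sham, with a median log2 fold change of -1.26 for Dbp, Tef, Nr1d1, Nr1d2, Per2, Per3 and Ciart, while Cry1, which was not in that set, rose by 1.18 ± 0.35 (SE, n = 4). If the rats were taken at different times of day, the genes of the opposite phase should move the other way. The median of Arntl, Npas2, Clock and Nfil3 was 0.60, consistent with such a difference, although Arntl, at 0.85 ± 0.44, and Npas2, at 0.34 ± 0.57, did not pass edgeR's test (n = 4). A direct effect of disease on the clock would give the same pattern, and the time of collection is not given in the sources used here for any group, so the clock changes under the drugs and between them are open in the same way. Within sham, Arntl ran from 10.2 to 98.5 CPM and Dbp from 73.3 to 243 CPM.

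For each of the 10 results tested by regrouping the libraries, 1 grouping, the real one, gave a result as large, which is 1 of 35 for each comparison, 1 of 70 for the genes reversed by each drug and 1 of 100 for the genes reversed by both and the correlation. Each share is under 0.05, and in that sense alone chance can be excluded for each result by itself. PAN against sham called 3231 genes, and the highest of the other 34 splits called 1214. That split put PAN library 2 with Sham libraries 1, 2 and 3, so that 3 of 4 libraries on each side kept their real label. It also put the lower proximal tubule scores on one side, at -1.44, -0.80, -0.0015 and -1.01 in that order. Sham library 4 and PAN libraries 1, 3 and 4, on the other side, stood at 0.0047, 0.16, 0.98 and 0.48. Why this split called so many genes was not tested. For the other comparisons, the real counts of 1470, 628, 2167, 867 and 108 stood against highest others of 4, 1, 2, 1 and 0 in edgeR's test, for PAN+MP against PAN, PAN+Pio against PAN, PAN+MP against sham, PAN+Pio against sham and PAN+Pio against PAN+MP. The reversed genes numbered 886 for methylprednisolone against 253 in the highest of 69 other assignments, and 532 for pioglitazone against 12, in each case the one that exchanges the PAN and drug labels. Both drugs reversed 475 against 1, and the correlation of drug effects was 0.756 against 0.738, a narrow margin, over 100 assignments.

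Some libraries stood apart from the other 3 of their group, with a gap to the nearest of them above Dixon's critical share of the group's range. There were 15 such cases among 255 pairs of gene and group, where chance gives about 1 in 20, or 12.8. Ctsl was low in Sham library 1, at 729 CPM against 883 to 897 CPM. Cdkn1a was low in Sham library 4, at 6.0 CPM against 11.4 to 12.4 CPM. Sham library 3 was high for Gpnmb, at 7.94 CPM against 5.42 to 5.59 CPM, and for Cidea, at 0.224 CPM against 0.0779 to 0.0885 CPM. Pbk was low in PAN library 4, at 7.77 CPM against 12.6 to 13.5 CPM. PAN+MP library 4 was high for Eln, at 9.88 CPM against 7.0 to 7.10 CPM, and for Fkbp5, at 210.5 CPM against 22.4 to 31.1 CPM. Mx2 was high in PAN+MP library 1, at 365 CPM against 95.5 to 113 CPM. PAN+Pio library 2 was low for Tpx2, at 9.98 CPM against 15.8 to 16.5 CPM, for Bub1b, at 3.72 CPM against 6.31 to 6.93 CPM, for C1qb, at 4.14 CPM against 6.20 to 6.69 CPM, and for Hist1h2bk, at 5.83 CPM against 11.5 to 12.6 CPM. PAN+Pio library 3 was low for Phlda3, at 6.56 CPM against 7.94 to 8.10 CPM, and for Cry1, at 3.91 CPM against 6.94 to 7.29 CPM, and high for Art3, at 2.73 CPM against 1.20 to 1.36 CPM.

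The direct test between the drugs called 108 genes, 73 higher and 35 lower under pioglitazone. Without PAN+MP library 2 or 3 edgeR called 0, with 1308 and 1263 genes at an unadjusted p under 0.05. DESeq2 called 286 on all libraries.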

How the results depend on the processing

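The tubule score as covariate, leaving out the 2 tagged libraries and limma-voom with weights were chosen after the data were seen. Whether higher or lower genes were more numerous turned over in each comparison with sham under some alternatives. The count reversed by methylprednisolone (886, range 628 to 1136) and the number of called list tests (48, range 42 to 59) stayed within 1.5 times in each of 21 and 23 alternatives. All of these list tests kept the preset correlation of 0.01. With an estimated correlation the list calls fell from 16 to 0 for PAN against sham, from 13 to 5 for PAN+MP against PAN and from 19 to 5 for PAN+Pio against PAN. Of 2616 gene values under alternatives, 2440 stayed on the same side of the threshold, 165 lost a call and 11 gained one. Of 154 named values, 118 never changed side. Direction was checked only for values called in the main fit, and 0 of those reversed. Where values moved, the cause was not tested.

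With DESeq2, PAN+Pio against PAN called 1076 genes, PAN+Pio against sham 1724 and PAN+Pio against PAN+MP 286, pioglitazone reversed 811, and the correlation of drug effects was 0.565. With no filter that correlation was 0.541. Fitting only the groups compared, which leaves fewer samples, called 2051 genes for PAN against sham, 509 for PAN+Pio against sham and 172 for PAN+Pio against PAN+MP. Requiring a fold of 1.5, which by construction removes small changes, left 1729 for PAN against sham, 1042 for PAN+MP against sham and 443 for PAN+Pio against sham. With the tubule score as covariate, PAN+MP against sham called 776, PAN+Pio against sham 488 and PAN+Pio against PAN+MP 196. Without the tagged libraries, PAN+Pio against sham called 507 and PAN+Pio against PAN+MP 15. With limma-voom and weights these were 1578 and 415.

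Leaving out 1 library at a time, which leaves fewer samples, gave 1978 to 4071 genes for PAN against sham (lowest without PAN library 3, highest without PAN library 2), 946 to 1387 for PAN+MP against PAN (PAN+MP library 3, PAN library 4) and 276 to 677 for PAN+Pio against PAN (PAN+Pio library 2, PAN library 4). It gave 726 to 2381 for PAN+MP against sham (Sham libraries 1 and 4), 334 to 1124 for PAN+Pio against sham (Sham library 1, PAN+Pio library 2) and 0 to 130 for PAN+Pio against PAN+MP (PAN+MP libraries 2 and 1). The 0 was edgeR's, with 1308 genes at an unadjusted p under 0.05 there. Pioglitazone reversed 250 to 613 genes and both drugs 238 to 551, and the correlation lay between 0.721 and 0.788.

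No paired analysis was possible because the count columns carry no replicate numbers. The pseudocount alternative did not apply, since the values are counts. At this depth the simulated recovery at a log2 change of 1 was 68% to 84% over the 5 comparisons simulated, so smaller changes can be missed.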

Other observations

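Further clock genes, picked after their values were seen, moved between PAN+MP and PAN. Per3, a period gene, rose by 2.08 ± 0.32 on the log2 scale, Tef by 2.08 ± 0.34 and Nr1d2, the clock repressor REV-ERB beta, by 1.36 ± 0.26 (SE, n = 4, edgeR). Arntl fell by 2.88 ± 0.47, Nfil3, a repressor of the opposite phase, fell by 2.03 ± 0.36, and Clock fell by 0.49 ± 0.09. In PAN+Pio against PAN, Cry1 fell by 1.69 ± 0.36, while Arntl stood at -0.37 ± 0.43 and Dbp at 1.33 ± 0.45, neither past edgeR's threshold. Without times of collection, these changes are not ascribed to the drugs.

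Of the genes changed by methylprednisolone against PAN, 579 had not been called in PAN against sham, and 96 of those changed by pioglitazone had not. A further 1036 genes were called in PAN+MP against sham and not in PAN against sham. That count was not taken under the alternatives, and the 2167 genes called in PAN+MP against sham, from which it comes, were 726 without Sham library 1, 988 without PAN+MP library 4 and 776 with the tubule score as covariate. Of the genes reversed by methylprednisolone 69 still differed from sham, and 51 of those reversed by pioglitazone did.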
